A study of Mus musculus with 62 samples.

How the data were processed

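White adipose tissue of female mice was studied by RNA sequencing in 62 libraries, 1 per sample. The sample descriptions give 3 arms: melanoma cells that cause cachexia (CAC), melanoma cells that do not (NCAC) and mock injection (Con). They also give 4 times after injection (2, 4, 6 and 8 weeks) and a replicate number. Arm, week and replicate were taken from those descriptions, because the treatment tag of every sample reads cachectic melanoma cells. This gives 12 groups of 5 libraries, except for CAC at 8 weeks with 7. The series record names athymic nude mice 2 months old, whereas the strain tag of every sample reads C57BL6/J, and the conflict could not be settled from the sources used here. The library protocol in the labels calls the replicates biological and also mentions a time point of 3 weeks after LLC cells, which no sample carries.

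RNA was extracted with Trizol, libraries were made with a stranded TruSeq mRNA kit and sequenced on an Illumina NovaSeq, per the labels. Reads were placed on the mouse genome build mm10, per the submitters' processing notes. The aligner, the counting tool, the annotation release and the number of reads per library are not given in the sources used here. The authors deposited 1 table of TPM (transcript abundance corrected for length and scaled to a fixed sum in each library) with 47643 gene symbols, and each library sums to 1000000 TPM with the 37 mitochondrially encoded genes included. The read depth is unknown, so no counting interval or detection limit is given for any value. Each symbol is 1 row, 244 symbols share a name with another symbol plus a suffix, and all were kept separate. Because the counting tool is unknown, values of near-identical genes (C4a and C4b, the Serpina3 family, Saa1 and Saa2, the Mup family, Mt1 and Mt2) may be split between copies and are uncertain individually. Coordinates were looked up by symbol in GENCODE M21 (GRCm38, the build also called mm10), where 45134 of the symbols were found.

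Each value was transformed to log2(TPM + 1). Genes with a mean of at least 0.5 TPM over the 62 libraries were tested, 14577 of the 47643 symbols, and a gene without variation in a comparison dropped out of it. Each of the 12 comparisons between arms at 1 week was fitted with limma 3.58.1 in R 4.3.3 on the libraries of the 2 groups alone (lmFit, then empirical Bayes with a mean-variance trend and a robust prior). The difference of the CAC effect between 8 and 2 weeks, between 8 and 6 weeks, the same for NCAC between 8 and 2 weeks, and the change of mock tissue between 2 and 8 weeks were fitted in the same way. All tests were two-sided, p-values were adjusted over the genes by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. The words rose and fell are used for called genes. Errors beside log2 changes are limma standard errors, and errors beside TPM are standard deviations.

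A set of 16 pathway lists and 14 cell marker lists with 377 genes was fixed before the data were examined, and 376 of the genes are in the table. Itgam of the macrophage list was not analysed here. The list of pancreas and gut genes had 2 tested members and was not tested. Each other list was tested with camera from limma at a preset correlation between genes of 0.01, adjusted over 348 tests, with camera at an estimated correlation and fry beside it. The results of fry are not reported here. Counts of called members are given over all genes and adjusted over the list alone. Of the 348 tests, 156 passed at the preset correlation and 0 with an estimated correlation, so list results rest on the counts of called members.

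The genes named in the text follow a rule fixed before the data were examined. For CAC against mock at each week it takes, among called genes with a mean of at least 10 TPM in the group with the higher level, the 10 with the largest rise and the 10 with the largest fall. For the other comparisons it takes 5 in each direction. From each list it takes up to 2 called members with the largest rise and 2 with the largest fall. It always takes Lep, Adipoq, Ucp1, Pnpla2, Lipe, Fasn, Scd1, Pck1, Fkbp5, Pdk4, Lcn2, Saa3, Azgp1, Col1a1 and Adgre1, and it skips predicted genes, symbols ending in Rik and mitochondrially encoded genes. Where a gene outside the rule is named, the text says that it was chosen after its values were seen.

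The fits were tested on simulated data made from each gene's mean over the libraries compared and its spread within groups. Noise was drawn independently for each gene. Among genes with a mean of at least 2 on the log2 scale, 100 were changed by 1 and 100 by 2. For CAC against mock at 8 weeks, 56 and 94 of these were recovered among 14577 genes, for CAC against mock at 6 weeks 46 and 94, for NCAC against mock at 8 weeks 49 and 87, for CAC against NCAC at 6 weeks 72 and 99, and for the CAC effect at 8 against 2 weeks 30 and 77, in each case with 0 of the wrong sign. Unchanged genes among all those called were 8 of 158, 8 of 148, 3 of 139, 13 of 184 and 10 of 117 in the same order. Structure that genes share in the real libraries was not simulated, so recovery and false calls there may differ. Libraries were checked for duplicates: the highest Pearson correlation between 2 libraries was 0.989, and at most 0.00701% of non-zero values were equal.

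Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter on low values, rescaling of each library by a median ratio over genes with at least 1 TPM in every library, all 62 libraries in 1 fit, limma library weights, the replicate number as a block, and each library left out in turn. Alternatives added after seeing the data were mitochondrially encoded genes left out with rescaling, libraries under 22% mitochondrial TPM left out (5 libraries), a covariate of 5 stromal markers that are not matrix proteins (Pdgfra, Dpp4, Cd34, Ly6a and Pi16), libraries with over 100 TPM of 7 urothelial transcripts (Upk1a, Upk2, Upk3a, Krt5, Krt20, Psca and Sprr1a) left out, and those transcripts as a covariate. For each gene count, the libraries of the comparison were also regrouped at random, up to 100 groupings with the real one included. Comparisons of single values used exact permutation tests, two-sided. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.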

Results

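White adipose tissue was sequenced from mice 2, 4, 6 and 8 weeks after they received melanoma cells that cause cachexia (CAC), a wasting of fat and muscle in cancer, melanoma cells that do not (NCAC), or a mock injection. The 62 libraries form 12 groups of 5, with 7 in the CAC group at 8 weeks. The number of reads behind each library is unknown, since the values are TPM and every library sums to 1000000. Between 11783 and 14470 genes reached at least 1 TPM in a library. Mitochondrially encoded genes took from 17.2% to 44.4% of a library's TPM. The series sets out to follow the tissue as cachexia develops, so each arm was compared with mock tissue of the same week, the cell-bearing arms with each other, and the differences between weeks.

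At 8 weeks Itih4, which encodes a secreted acute-phase protein of the inter-alpha-trypsin inhibitor family (chromosome 14, 30886476 to 30902353 on GRCm38), averaged 895 ± 427 TPM (SD, n = 7) in CAC tissue and 5.62 ± 1.86 TPM (n = 5) in mock tissue. Its log2 change was 6.87 (SE 0.46, limma adjusted p = 1.52e-05), and 7 of 7 CAC libraries lay above every mock library. Fkbp5, a co-chaperone of the glucocorticoid receptor that glucocorticoids induce (chromosome 17, 28399094 to 28517527), rose from 12.2 ± 5.97 to 219 ± 133 TPM, a log2 change of 3.76 (SE 0.62, limma adjusted p = 0.0118). Hp, the haemoglobin-binding plasma protein haptoglobin (chromosome 8, 109575128 to 109579172), rose from 464 ± 224 to 9050 ± 6139 TPM, a log2 change of 3.95 (SE 0.71, limma adjusted p = 0.0160). For both genes 6 of 7 CAC libraries lay above every mock library. Col1a1, the main chain of type I collagen (chromosome 11, 94936224 to 94953042), fell by 3.15 on the log2 scale (SE 0.62, limma adjusted p = 0.0210), from 483 ± 612 to 35.2 ± 18.4 TPM, with 7 of 7 CAC libraries below every mock library. Of 23 other settings the calls of Itih4, Fkbp5, Hp and Col1a1 held in 22, 21, 21 and 17, and leaving out 1 library took the limma adjusted p of Col1a1 to 0.0525 at most.

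In all, limma called 158 genes higher and 290 lower in CAC than in mock tissue at 8 weeks, 125 and 202 of them by at least 2-fold, among 14577 tested. With the mitochondrially encoded genes left out the split was 248 higher and 1824 lower, with a stromal covariate 278 and 113, with all 62 libraries in 1 fit 536 and 450, and with library weights 467 and 995. The count of 448 moved to 172, 236, 169 and 131 without CAC replicates 4, 5, 6 and 7, and to 209, 238 and 220 without mock replicates 2, 4 and 5. With the sum of 7 urothelial transcripts as a covariate it was 67, with the libraries over 100 TPM in that sum left out 0, and with median-ratio rescaling 1435. Leaving out those libraries drops 5 of 7 CAC and 2 of 5 mock libraries, so 0 calls there cannot tell a lost change from too few libraries. Every count given under that setting with 8-week CAC libraries shares this limit.

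Among the largest rises at 8 weeks were transcripts of plasma proteins that the liver usually secretes. Fga, the fibrinogen alpha chain (chromosome 3, 83026076 to 83033627), was at 330 ± 500 TPM in CAC and 0.0162 ± 0.0164 TPM in mock tissue, a log2 change of 5.75 (SE 1.41, limma adjusted p = 0.0455). Fgl1, a fibrinogen-like secreted protein, rose by 3.94 (SE 0.74), and the serine protease inhibitors Serpina3k and Serpina3m rose by 4.56 (SE 0.55) and 4.29 (SE 0.60). The metal-binding metallothioneins Mt2 and Mt1 rose by 4.88 (SE 0.99) and 3.87 (SE 0.79), and the lipid carrier Apod by 3.86 (SE 0.69). The call of Fga held in 7 of 23 other settings, with log2 changes from 1.42 to 8.71, those of Mt1 and Mt2 in 16 each, and those of the other 4 in 20 to 22. On leaving out 1 library the limma adjusted p reached 0.0923 for Fga, 0.0535 for Mt2 and 0.0546 for Mt1. Reads of Mt1 and Mt2, and of the Serpina3 genes, may be shared between these near-identical copies.

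The largest fall at 8 weeks was that of Nnat (chromosome 2, 157560078 to 157562522), a small membrane protein, at −4.85 (SE 1.00, limma adjusted p = 0.0243). Oxtr, the oxytocin receptor, changed by −3.94 (SE 0.72), and Npr3, which clears natriuretic peptides that stimulate lipolysis, by −3.20 (SE 0.48). The secreted matrix proteins Spon2 and Cilp changed by −3.20 (SE 0.54) and −3.19 (SE 0.42). Col6a3 and Col6a2, chains of the type VI collagen that surrounds adipocytes, changed by −3.18 (SE 0.60) and −2.97 (SE 0.56). The steroid-metabolising enzyme Akr1c14 (−3.08, SE 0.67) and the synuclein Sncg (−2.94, SE 0.71) completed the 10 largest falls. Leaving out 1 library could end the calls of Nnat, Akr1c14 and Sncg (limma adjusted p up to 0.0568, 0.0712 and 0.0883), which held in 13, 13 and 8 of 23 other settings, while those of Oxtr, Npr3, Spon2, Cilp, Col6a3 and Col6a2 held in 19 to 21.

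Of 20 genes of the extracellular matrix list, 13 fell at 8 weeks and 7 were not called (16 fell adjusted over the list alone), and 20 of 20 had negative log2 changes with a median of −1.89. The list passed camera from limma at adjusted p = 3.76e-13 with the preset correlation and not at adjusted p = 0.577 with an estimated correlation. The count of 13 was 8 without CAC replicate 7 and 8 without mock replicate 5, 6 with a stromal covariate (median −1.55), 4 with the urothelial covariate (median −1.96) and 0 with the urothelial libraries left out (median −1.47). Of 10 markers of fibroblasts and adipocyte progenitors, 4 fell (5 adjusted over the list alone): Fbn1 (−2.28, SE 0.33) and Lum (−2.10, SE 0.51), both of the matrix scaffold, with Dpt and Mfap5, which were chosen after their values were seen. The call of Lum held in 9 of 23 other settings and that of Fbn1 in 21. The fibroblast count was 2 without CAC replicates 4, 5, 6 or 7 and without mock replicates 2, 4 or 5, and 1 with the urothelial covariate and 0 with the urothelial libraries left out, with medians of −0.71 and −0.77 against −0.73. Of 8 mesothelial markers 1 fell, the surface protein Msln (−1.96, SE 0.33), and 3 fell adjusted over the list alone.

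Of 15 genes of the glucocorticoid and fasting response, 4 rose at 8 weeks and 11 were not called (7 rose adjusted over the list alone): Mt2, Mt1 and Fkbp5, with Tsc22d3 (1.65, SE 0.34), an anti-inflammatory target of glucocorticoids that was chosen after its values were seen. The count of 4 was 1 without CAC replicates 6 or 7 and 2 without mock replicate 2, 1 with the urothelial covariate and 0 with the urothelial libraries left out, with medians of 1.20 and 0.69 against 1.32. Of 18 genes of the acute phase and IL-6 family response, 5 rose (8 rose and 1 fell adjusted over the list alone). They were Hp and the protease inhibitor Serpina3n (3.45, SE 0.59), and, chosen after their values were seen, the serum amyloids Saa1 and Saa2, listed at 0 in every mock library, and the oncostatin receptor Osmr (1.30, SE 0.33). That count was 2 without CAC replicates 2, 4, 5, 6 or 7 and without mock replicates 1, 4 or 5, 3 without mock replicate 2, and 8 without CAC replicate 3. It was 0 with the urothelial covariate and 0 with the urothelial libraries left out, with medians of 1.02 and 0.91 against 1.19. The camera calls of the glucocorticoid list (adjusted p = 2.18e-08) and of the acute phase list (adjusted p = 9.11e-08) were lost with an estimated correlation (adjusted p = 0.577 for both).

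Of 12 lipolysis genes 2 rose and 1 fell at 8 weeks (3 and 3 adjusted over the list alone): Abhd5, the activator of the first triglyceride lipase, rose by 1.00 (SE 0.21), Azgp1, a secreted lipid-mobilising factor, rose by 2.17 (SE 0.53), and Npr3 fell. The first triglyceride lipase itself, Pnpla2, was at 2557 ± 427 TPM in CAC and 1529 ± 371 TPM in mock tissue and was not called (log2 change 0.76, SE 0.21, limma adjusted p = 0.0688). Leptin, encoded by Lep (chromosome 6, 29060220 to 29073877), was at 20.6 ± 19.0 and 165 ± 172 TPM and was not called either (−3.44, SE 1.01, limma adjusted p = 0.0815). Of 16 adipocyte identity genes 1 rose, the adipokine Cfd (0.92, SE 0.21), with 1 rise and 2 falls adjusted over the list alone. Of 14 genes of fatty acid synthesis 1 rose, the transcription factor gene Mlxipl (0.99, SE 0.24), with 2 rises adjusted over the list alone. Of 15 genes of cholesterol synthesis 1 rose, the enzyme gene Cyp51 (2.18, SE 0.43), also 1 adjusted over the list alone. The calls of the 5 genes that rose could be lost by leaving out 1 library, with limma adjusted p up to 0.0636 for Abhd5, 0.103 for Azgp1, 0.0852 for Cfd, 0.0978 for Mlxipl and 0.0535 for Cyp51, and held in 13, 8, 7, 7 and 17 of 23 other settings. Adipoq, Ucp1, Lipe, Fasn, Scd1, Pck1, Pdk4, Lcn2, Saa3 and Adgre1 were not called at 8 weeks, and their limma adjusted p ran from 0.143 for Pck1 to 0.983 for Adipoq.

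No member of the other lists was called at 8 weeks in CAC against mock tissue. Of 15 proliferation genes 15 had negative log2 changes and 13 fell adjusted over the list alone (median −1.05, camera from limma adjusted p = 2.52e-06, adjusted p = 0.587 with an estimated correlation). A part of this gap rests on mock replicate 2. Its mean log2 level over the proliferation list was 3.68, against 1.38 to 2.34 in the other mock libraries and 0.87 to 1.49 in CAC libraries. Adjusted over the list alone, 1 of 10 triglyceride synthesis genes rose, 2 of 5 neutrophil markers rose and 1 fell, 1 of 6 T cell markers fell and 1 of 10 endothelial markers fell. No member passed adjusted over the list alone in 15 lists. These were thermogenic adipocyte (14 tested), fatty acid oxidation (16), oxidative phosphorylation (23), unfolded protein and stress response (14), autophagy and proteolysis (14), interferon response (15) and circadian clock (14), and the markers of macrophages (11), B cells and lymph nodes (7), NK cells (5), mammary epithelium (4), skeletal muscle (10), erythroid blood (5), melanocytes and melanoma (4) and ovary (3). The unadjusted p was under 0.05 for 2999 of all tested genes in this limma comparison.

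**Figure D1:**
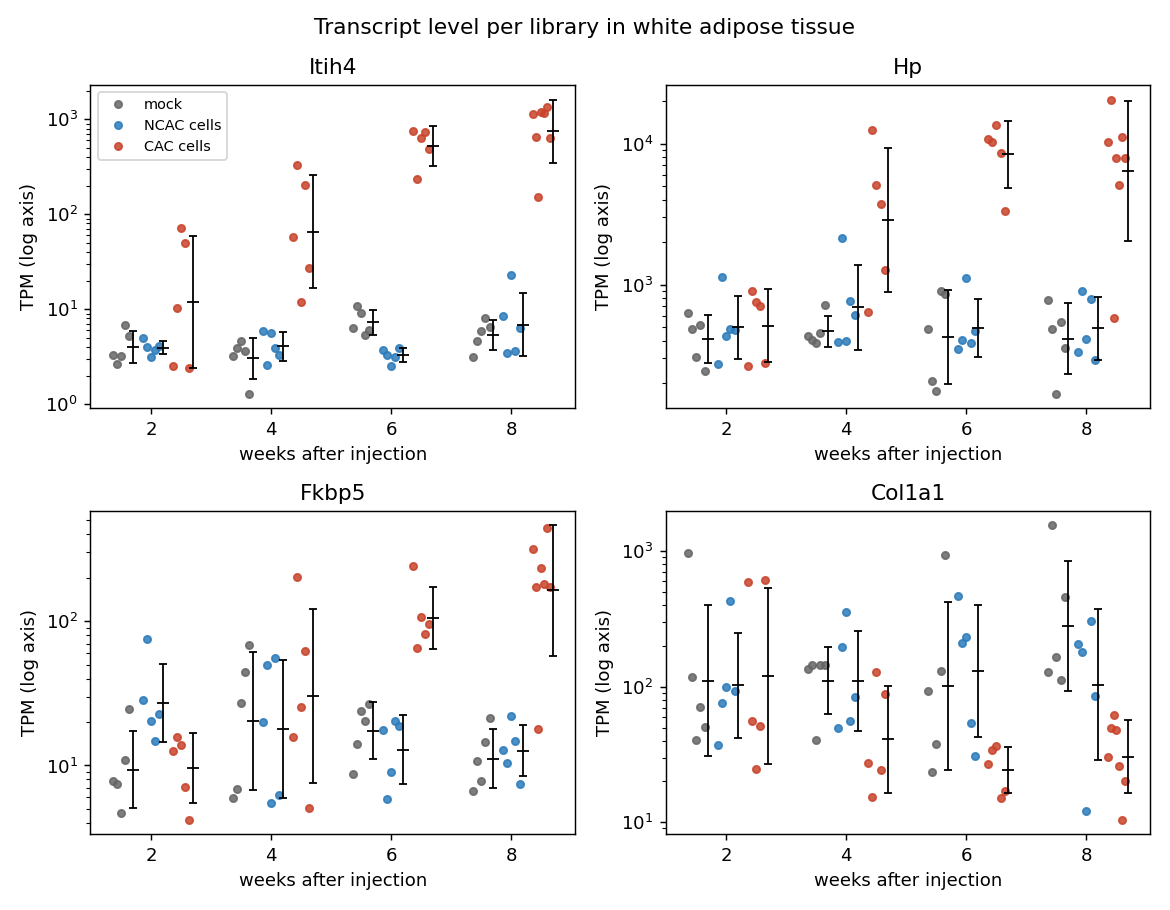
TPM of Itih4, Hp, Fkbp5 and Col1a1 in each of the 62 libraries (points, log axis) against weeks after injection, with the mean and SD of log10 TPM of each group as a bar beside the points. At 8 weeks the CAC libraries lie between 151 and 1340 TPM for Itih4 and the mock libraries between 3.13 and 8.05 TPM.

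At 6 weeks Itih4 and Hp had the largest called rises in CAC against mock tissue. Itih4 was at 570 ± 215 TPM (SD, n = 5) against 7.55 ± 2.35 TPM (n = 5), a log2 change of 5.99 (SE 0.31, limma adjusted p = 6.81e-06). Hp rose from 524 ± 342 to 9271 ± 3770 TPM, a change of 4.31 (SE 0.52, limma adjusted p = 0.00474), and Fkbp5 from 18.8 ± 7.40 to 118 ± 70.2 TPM, a change of 2.53 (SE 0.37, limma adjusted p = 0.0138). Apod rose by 3.95 (SE 0.27) and the iron-siderophore-binding lipocalin Lcn2 by 3.84 (SE 0.50). Cxcl9, a chemokine that interferon gamma induces, fell by 2.42 (SE 0.19, limma adjusted p = 0.000178), from 28.9 ± 2.12 to 4.73 ± 1.54 TPM. For each of these 6 genes, 5 of 5 CAC libraries lay beyond every mock library.

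At this week limma called 45 genes higher and 7 lower in CAC than in mock tissue, 43 and 6 by at least 2-fold, among 14571 tested. The split was 131 and 57 with median-ratio rescaling, 68 and 57 without the mitochondrially encoded genes, 142 and 43 with all 62 libraries in 1 fit and 1713 and 1045 with library weights. The count of 52 was 27, 33 and 22 without CAC replicates 1, 2 and 4, it was 25, 34 and 34 without mock replicates 1, 3 and 4, and it was 159 without mock replicate 5. With the urothelial covariate it was 10, and with the urothelial libraries left out 5, a setting that drops 3 of 5 CAC and 1 of 5 mock libraries. The other large rises were those of Mt2 (4.21, SE 0.67), the leucine-rich glycoprotein Lrg1 (3.59, SE 0.65), Serpina3m (3.49, SE 0.20), the secreted protease inhibitor Wfdc21 (3.40, SE 0.34), Serpina3n (3.23, SE 0.33) and Mt1 (3.11, SE 0.34). The other falls were those of the eosinophil ribonuclease Rnase2a (−2.69, SE 0.47), the urinary lipocalin Mup3 (−2.14, SE 0.36) and the esterase Pon1 (−1.81, SE 0.30), and, chosen after their values were seen, Gbp10, Prnd and Cox4i2. Of 21 other settings the calls of Mt2, Lrg1, Rnase2a, Mup3 and Pon1 held in 11, 10, 10, 8 and 9, and leaving out 1 library could end each of them.

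Glucocorticoid and fasting response genes rose in 3 of 15 cases at 6 weeks (Mt2, Mt1 and Fkbp5; 4 adjusted over the list alone). Acute phase genes rose in 3 of 18 cases (Hp, Lcn2 and Serpina3n; 11 adjusted over the list alone), with a median log2 change of 1.27, and the count of 3 over all genes was 5 without CAC replicate 5 and 7 without mock replicate 5. There were 0 glucocorticoid and 2 acute phase calls with the urothelial covariate (medians 0.47 and 1.26), and 0 and 1 with the urothelial libraries left out, where the medians were 0.11 and 1.14. Their camera calls from limma (adjusted p = 1.32e-07 and 2.1e-12) were lost with an estimated correlation (adjusted p = 0.577 and 0.534). No gene of any other list was called over all genes. The 20 matrix genes had a median of −1.20, with 1 fall adjusted over the list alone, and Col1a1 itself was not called (−2.01, SE 0.80, limma adjusted p = 0.442). Mock replicate 5 stood apart here. Its mean log2 level over the matrix list was 7.86, against 4.35 to 6.15 in the other mock libraries and 4.25 to 5.34 in CAC libraries. Log2 changes were positive for 14 of 14 thermogenic genes (median 1.23) and 23 of 23 oxidative phosphorylation genes (median 0.32), with none called adjusted over the list alone. A part of both rests on mock replicate 5. Its mean log2 level was 1.71 over the thermogenic list (2.64 to 6.05 in the other mock, 4.08 to 5.98 in CAC libraries). Over the oxidative phosphorylation list it was 7.51 (7.89 to 8.34 in the other mock, 8.16 to 8.45 in CAC libraries). Lep was at 20.01 ± 23.7 against 235 ± 172 TPM and was not called (−3.98, SE 0.94, limma adjusted p = 0.127), and neither was Ucp1 (3.72, SE 1.65, limma adjusted p = 0.513).

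Earlier, at 4 weeks, the chemokine gene Ccl8 (chromosome 11, 82115185 to 82116799) rose from 8.97 ± 4.15 TPM (SD, n = 5) in mock to 73.3 ± 10.7 TPM (n = 5) in CAC tissue, with 5 of 5 CAC libraries above every mock library. Its log2 change of 3.01 (SE 0.29, limma adjusted p = 0.00548) was the 1 call of that week, and 405 genes had an unadjusted p under 0.05. Ccl8 was not called with all 62 libraries in 1 fit (limma adjusted p = 0.73), where 1 other gene was, nor with the stromal covariate or with the urothelial libraries left out, and it stayed called in 17 of 20 other settings. At 2 weeks the 1 called gene was Ccdc36, which encodes a protein of meiotic recombination (chromosome 9, 108403611 to 108428484). It rose by 1.86 (SE 0.20, limma adjusted p = 0.0222) and falls outside the naming rule, so it was chosen after its values were seen. It was not called without CAC replicates 1, 3, 4 or 5 or without mock replicates 2, 3, 4 or 5, when the count was 0, and 503 genes had an unadjusted p under 0.05. Library weights gave 670 calls at 2 weeks, 326 higher and 344 lower.

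Across weeks, 34 of the 45 genes higher in CAC at 6 weeks were also called higher at 8 weeks, where 0.488 would be shared by independent lists, and 3 of the 7 lower genes were called lower again, against 0.139. The weeks have separate mock groups. The 158 genes higher at 8 weeks had median log2 changes of 0.06, 0.39, 0.99 and 1.45 at 2, 4, 6 and 8 weeks, and the 290 lower genes had medians of −0.10, −0.56, −0.85 and −1.25. These genes were chosen by their call at 8 weeks. Itih4 changed by 1.46 (SE 0.83), 4.03 (SE 0.79), 5.99 (SE 0.31) and 6.87 (SE 0.46) over these weeks.

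The difference between the CAC effects at 8 and at 2 weeks was tested directly. Itih4 gained 5.41 (SE 0.97, limma adjusted p = 0.0388), Serpina3m gained 4.24 (SE 0.77, limma adjusted p = 0.0388), the secreted liver-type protein fetuin-B, Fetub, gained 3.29 (SE 0.44, limma adjusted p = 0.0016) and Hsd11b1, the enzyme that regenerates active glucocorticoid, gained 2.60 (SE 0.47, limma adjusted p = 0.0388). The lysozyme gene Lyz1 changed by −2.61 (SE 0.48, limma adjusted p = 0.0426). Chosen after their values were seen, Tekt1 gained 1.58, and Usp50 and Ccdc36 changed by −1.72 and −1.85. Of 33 other settings the calls of Itih4 and Serpina3m held in 8 each, that of Hsd11b1 in 12, that of Lyz1 in 11 and that of Fetub in 32. The 8 calls, 5 higher and 3 lower, were 68 without CAC replicate 3 of week 8, and 4 to 5 when any of 18 other libraries was left out, and 0 with the urothelial libraries left out. Between 8 and 6 weeks limma called 0 genes as different in CAC effect, with 116 at an unadjusted p under 0.05.

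In NCAC tissue limma called 0 genes against mock tissue at 2, 4, 6 and 8 weeks (n = 5 in each group), with 234, 115, 205 and 181 genes at an unadjusted p under 0.05. With library weights the counts were 230 at 2 weeks (110 higher, 120 lower) and 1078 at 6 weeks (256 higher, 822 lower). Itih4 was at 8.96 ± 8.06 TPM in NCAC and 5.62 ± 1.86 TPM in mock tissue at 8 weeks, Fkbp5 at 13.5 ± 5.56 and 12.2 ± 5.97 TPM, and Lep at 203 ± 179 and 165 ± 172 TPM. Thermogenic genes had negative log2 changes in 14 of 14 cases at 8 weeks (median −1.60), none of them called over all genes or adjusted over the list alone. At 2 weeks 10 of 14 circadian clock genes passed adjusted over the list alone, 7 higher and 3 lower, and 0 over all genes. The NCAC effect did not differ between 8 and 2 weeks for any gene in limma (0 called, 182 at an unadjusted p under 0.05). Mock tissue itself had 0 genes called between 2 and 8 weeks, with 564 at an unadjusted p under 0.05. Library weights gave 6 and 355 calls for these last 2 comparisons.

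**Figure D2:**
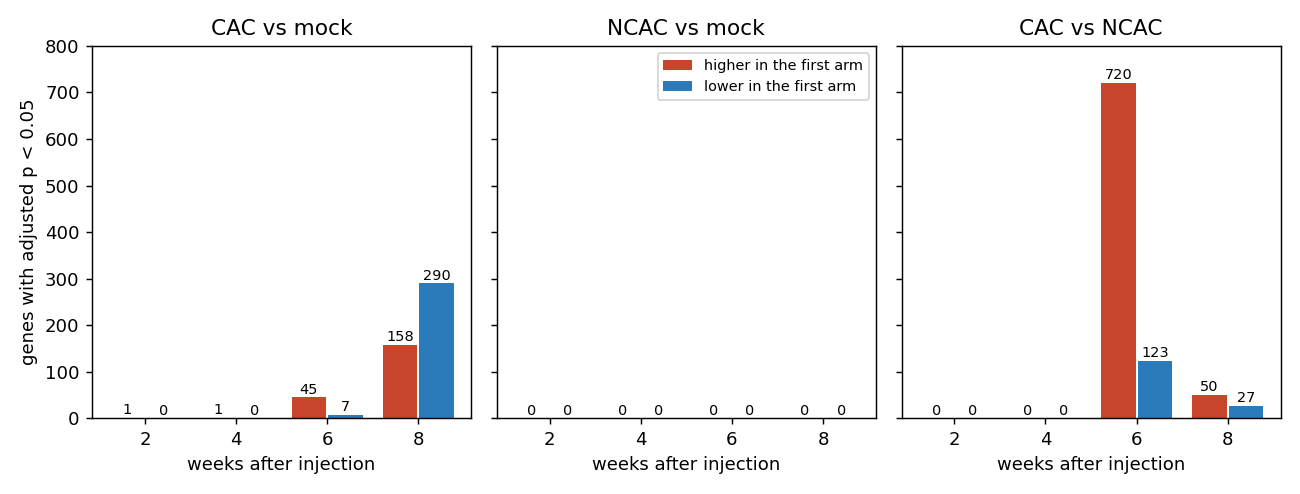
Number of genes called by limma (vertical axis, from 0) against weeks after injection for CAC against mock, NCAC against mock and CAC against NCAC tissue, with higher and lower genes as separate bars. CAC against mock reaches 158 higher and 290 lower genes at 8 weeks, and NCAC against mock has 0 at each week.

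Tissue of the CAC and NCAC arms was compared to separate the response to cachexia-causing cells from the response to melanoma cells in general. At 6 weeks Itih4 was at 570 ± 215 TPM (SD, n = 5) in CAC and 3.31 ± 0.53 TPM (n = 5) in NCAC tissue, a log2 change of 6.94 (SE 0.28, limma adjusted p = 7.33e-07). Fkbp5 was at 118 ± 70.2 against 14.3 ± 6.43 TPM, a change of 2.93 (SE 0.40, limma adjusted p = 0.00408), and Apod changed by 4.38 (SE 0.27, limma adjusted p = 2.11e-05). For these 3 genes 5 of 5 CAC libraries lay above every NCAC library. Among the falls, Oxtr changed by −3.65 (SE 0.66), the membrane protein gene Mmd2 by −3.55 (SE 0.62), Rnase2a by −3.48 (SE 0.69), Spon2 by −2.69 (SE 0.55) and Alb, serum albumin, by −2.69 (SE 0.39). The calls of Rnase2a and Spon2 held in 15 and 13 of 20 other settings, and those of the other genes named here in 18 to 20.

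The epithelial transcripts Sprr1a (5.33, SE 1.28), Upk3a (4.48, SE 1.10; chromosome 15, 85017141 to 85022547) and Psca (4.32, SE 1.07), of a cornified envelope protein, a uroplakin of the bladder lining and a surface antigen, also stood among the 5 largest rises at 6 weeks against NCAC. Their limma adjusted p were 0.0407, 0.0442 and 0.0456, leaving out 1 library took these to 0.0993, 0.104 and 0.106 at most, and each call held in 8 of 20 other settings. They are 3 of 7 urothelial transcripts whose sum ran from 3.65 to 955 TPM in CAC libraries and reached at most 2.22 TPM in NCAC libraries of that week, and libraries of all 3 arms exceeded 100 TPM at some week.

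**Figure D3:**
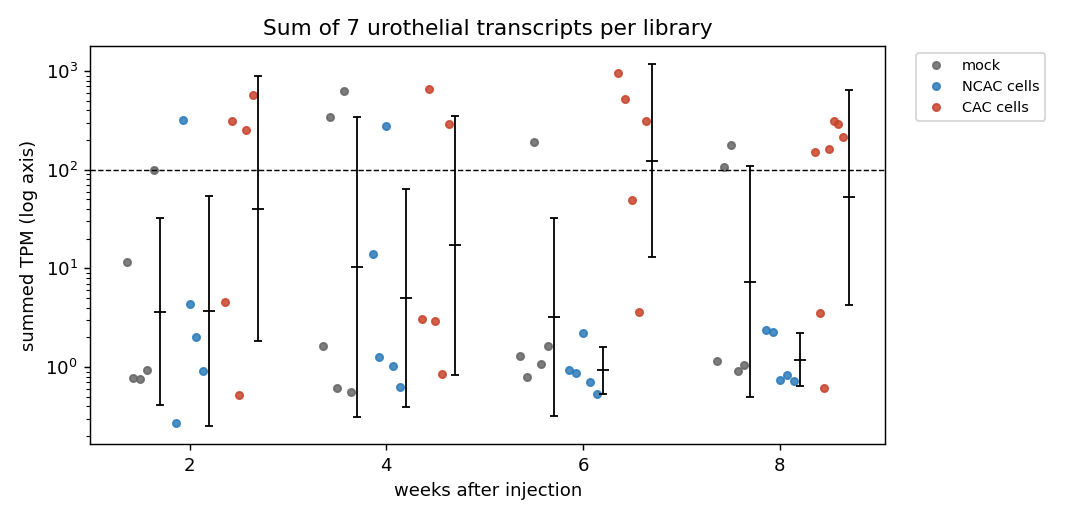
Sum of the TPM of 7 urothelial transcripts in each of the 62 libraries (points, log axis) against weeks after injection, with the mean and SD of the log10 sum of each group as a bar and a dashed line at 100 TPM. Above the line lie 13 of 22 CAC, 2 of 20 NCAC and 5 of 20 mock libraries.

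For CAC against NCAC tissue at 6 weeks limma called 720 genes higher and 123 lower, 210 and 71 by at least 2-fold, among 14576 tested. The median log2 change of all genes was 0.13 in the deposited TPM and −0.02 with median-ratio rescaling or without the mitochondrially encoded genes, where the splits were 504 and 469, and 332 and 336. Small rises in this comparison are therefore relative to a shift of that size. Library weights gave 2675 higher and 632 lower genes. The count of 843 was 305, 404 and 360 without CAC replicates 1, 2 and 4, and 400, 210, 1682 and 286 without NCAC replicates 1, 2, 3 and 4. With the urothelial covariate it was 4, and with the urothelial libraries left out 62, a setting that drops 3 of 5 CAC libraries.

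Acute phase genes rose in 8 of 18 cases at 6 weeks against NCAC (11 adjusted over the list alone), among them Hp (4.10, SE 0.41) and Lcn2 (3.99, SE 0.51), and this count was 5 without CAC replicates 1 or 4 or NCAC replicates 2 or 4. Glucocorticoid response genes rose in 4 of 15 cases (6 adjusted over the list alone): Mt2 (4.24, SE 0.49), Mt1 and Fkbp5, with Ddit4, chosen after its values were seen. Endothelial markers rose in 6 of 10 cases (8 adjusted over the list alone), among them the von Willebrand factor gene Vwf (0.94, SE 0.23) and the VEGF receptor gene Flt1 (0.73, SE 0.12). The endothelial count was 1 without CAC replicates 1, 2 or 4 or NCAC replicates 1, 2 or 4, 2 without NCAC replicate 5, and 2 without the mitochondrially encoded genes. Matrix genes fell in 2 of 20 cases (11 adjusted over the list alone), Col3a1 (−2.21, SE 0.46) and Col6a2 (−2.16, SE 0.48), and of the fibroblast markers Fbn1 fell (−1.93, SE 0.46; 5 adjusted over the list alone). Of 20 other settings the calls of Vwf, Col3a1, Col6a2 and Fbn1 held in 7, 13, 10 and 9. The matrix count was 0 without CAC replicates 1, 4 or 5 or NCAC replicates 1 or 2, 1 without CAC replicate 2 and 10 without NCAC replicate 5. The fibroblast count was 0 without CAC replicates 1, 2, 4 or 5 or NCAC replicates 1, 2 or 4, and 3 without NCAC replicate 5. With median-ratio rescaling the matrix count was 11 and the fibroblast count 3, and without the mitochondrially encoded genes 5 and 3. Each of these 5 lists had 0 calls with the urothelial covariate, where the median changes went from −1.01 to −1.56 for matrix, −0.92 to −1.60 for fibroblast, 1.52 to 1.05 for acute phase, 0.74 to 0.42 for glucocorticoid and 0.64 to 0.41 for endothelial genes. With the urothelial libraries left out 4 acute phase and 2 glucocorticoid genes were called and 0 of the other 3 lists, at medians of 1.43, 0.53, −1.14 (matrix), −1.10 (fibroblast) and 0.60 (endothelial). The camera calls from limma of the acute phase, glucocorticoid, endothelial, matrix and fibroblast lists were each lost with an estimated correlation (adjusted p = 0.577).

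Of 12 lipolysis genes 2 rose at 6 weeks against NCAC (2 adjusted over the list alone), Abhd5 (0.73, SE 0.17) and Pnpla2 (0.65, SE 0.16). Of 10 triglyceride synthesis genes 2 rose (2 rose and 1 fell adjusted over the list alone), Lpin1 (0.76, SE 0.19) and Gpam (0.71, SE 0.16), and of 14 fatty acid synthesis genes 1 rose (3 adjusted over the list alone), the desaturase gene Scd1 (1.27, SE 0.26). Abhd5, Pnpla2, Lpin1 and Gpam each stayed called in 7 of 20 other settings and Scd1 in 13 of 20. On leaving out 1 library their limma adjusted p reached 0.0862, 0.1, 0.108, 0.0824 and 0.0621 in turn. Pnpla2 was at 2644 ± 446 TPM in CAC and 1679 ± 274 TPM in NCAC tissue. Further called members were 2 of 14 autophagy genes, Map1lc3b (0.85, SE 0.15) and Ulk1 (0.66, SE 0.14), 2 of 14 clock genes, Cry1 (1.16, SE 0.22) and Per2 (0.80, SE 0.20), 1 of 15 cholesterol synthesis genes, Cyp51 (2.06, SE 0.40), and 1 of 14 stress response genes, Dnajb9 (0.55, SE 0.15). So were 2 of 11 macrophage markers, Gpnmb (2.34, SE 0.47) and Cd14 (1.41, SE 0.15), 1 of 5 neutrophil markers, Csf3r (1.00, SE 0.18), and the muscle genes Myh4 (4.06, SE 0.99) and Atp2a1 (3.46, SE 0.88). Of 20 other settings Map1lc3b, Cd14 and Csf3r stayed called in 18 each, Gpnmb in 17, Cyp51 in 16, Cry1 in 15, Ulk1 in 11, Myh4 in 6, Per2 and Atp2a1 in 5 each and Dnajb9 in 4. The 2 of 10 muscle genes (7 adjusted over the list alone) became 0 without CAC replicates 1, 2, 4 or 5 or NCAC replicates 1, 2, 4 or 5, 0 with the urothelial covariate (median 0.64 against 2.30), and 4 without CAC replicate 3. At 6 weeks the mean log2 level over the muscle list ran from 2.31 to 6.26 in CAC, 0.61 to 3.70 in NCAC and 0.93 to 8.56 in mock libraries. Mock replicates 1 and 3, at 7.05 and 8.56, lay above every CAC library. Muscle carried into the libraries was not tested as a source. Lep (−3.57, SE 1.08, limma adjusted p = 0.0794) and Col1a1 (−2.38, SE 0.68, limma adjusted p = 0.0697) were not called.

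At 8 weeks Itih4 was at 895 ± 427 TPM (SD, n = 7) in CAC and 8.96 ± 8.06 TPM (n = 5) in NCAC tissue, a log2 change of 6.54 (SE 0.55, limma adjusted p = 0.000306). Ccl8 was at 290 ± 249 against 18.8 ± 15.1 TPM, a change of 3.89 (SE 0.66, limma adjusted p = 0.0248). Cidea, which encodes a lipid droplet protein abundant in brown fat, was at 411 ± 200 against 81.8 ± 131 TPM, a change of 3.28 (SE 0.64, limma adjusted p = 0.0442), and Cpt1b, the carnitine transferase that admits fatty acids to mitochondria, changed by 2.96 (SE 0.55, limma adjusted p = 0.0409). For Itih4 and Ccl8 7 of 7 CAC libraries lay above every NCAC library, and for Cidea and Cpt1b 4 of 7. Apod, Serpina3k and Fgl1 rose by 4.07 (SE 0.77), 3.98 (SE 0.65) and 3.88 (SE 0.75). Npr3, Lyz1, Alb, Rnase2a and Smim5 changed by −3.32 (SE 0.65), −2.56 (SE 0.32), −2.49 (SE 0.45), −2.36 (SE 0.37) and −2.13 (SE 0.40). Of 23 other settings the call of Itih4 held in 21, that of Lyz1 in 20, that of Rnase2a in 15, that of Serpina3k in 14, that of Ccl8 in 11, those of Cpt1b, Apod, Fgl1, Npr3, Alb and Smim5 in 8 each and that of Cidea in 7. Leaving out 1 library took the limma adjusted p of the last 7 to between 0.122 (Alb) and 0.162 (Npr3).

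Thermogenic genes rose in 3 of 14 cases at 8 weeks against NCAC, Cidea, Cpt1b and, chosen after its values were seen, Cox7a1, and 11 rose adjusted over the list alone. All 14 had positive log2 changes (median 2.22, camera from limma adjusted p = 3.76e-13, adjusted p = 0.534 with an estimated correlation). The count of 3 was 0 without CAC replicates 1, 2, 4, 5, 6 or 7 or NCAC replicates 1, 2, 4 or 5, it was 5 without CAC replicate 3 and 11 without NCAC replicate 3. Ucp1, the uncoupling protein of brown fat, was at 428 ± 322 TPM in CAC, 102 ± 209 TPM in NCAC and 777 ± 973 TPM in mock tissue and was not called (4.36 against NCAC, SE 1.09, limma adjusted p = 0.0862). Acute phase genes rose in 4 of 18 cases (10 adjusted over the list alone): Hp (3.70, SE 0.70) and Serpina3n (3.11, SE 0.56), with Socs3 and Osmr, chosen after their values were seen. The calls of Hp and Serpina3n held in 8 of 23 other settings each. The acute phase count was 0 without CAC replicates 1, 4, 5, 6 or 7 or NCAC replicates 1, 2, 4 or 5, 1 without CAC replicate 2 and 8 without CAC replicate 3. Of the glucocorticoid response genes Fkbp5 rose (3.60, SE 0.61), and 7 rose and 1 fell adjusted over the list alone. That call was lost when any of 9 libraries was left out, namely CAC replicates 1, 4, 5, 6 and 7 and NCAC replicates 1, 2, 4 and 5, and 5 genes were called without CAC replicate 3 and 4 without NCAC replicate 3. The 3 lists had 0 calls with the urothelial covariate and 0 with the urothelial libraries left out. The thermogenic median was 2.17 and 2.16 there, against 2.22, while the acute phase median went from 1.30 to 0.79 and 0.88 and the glucocorticoid median from 1.27 to 0.68 and 0.64.

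The comparison of CAC with NCAC tissue at 8 weeks had 50 genes higher and 27 lower in limma, 91 and 115 without the mitochondrially encoded genes, 350 and 261 with all 62 libraries in 1 fit, and 1151 and 1910 with library weights. The count of 77 was 24, 405, 8, 30, 23 and 8 without CAC replicates 1, 3, 4, 5, 6 and 7, and 14, 7, 1253, 8 and 8 without NCAC replicates 1 to 5 in turn. With the urothelial covariate it was 1, and with the urothelial libraries left out 0, a setting that drops 5 of 7 CAC libraries. At 2 and 4 weeks limma called 0 genes between these arms, with 528 and 648 at an unadjusted p under 0.05. The count was 11 at 2 weeks with library weights, 1 at 2 weeks without NCAC replicate 4 and 1 at 4 weeks without CAC replicate 1.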

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

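The tests of liver tissue, bladder tissue, scaling, stromal share and a single mock library for the 3 weighed patterns were chosen after the results they address were seen, whereas the random regroupings of the libraries and the tests of the CAC effect at 8 against 2 weeks were planned.

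The CAC effect on 8 genes was called as different between 8 and 2 weeks by a test of the difference itself in limma, with log2 differences of 5.41 for Itih4, 4.24 for Serpina3m, 3.29 for Fetub, 2.6 for Hsd11b1, 1.58 for Tekt1, −1.72 for Usp50, −1.85 for Ccdc36 and −2.61 for Lyz1. These calls depend on the libraries: 4 to 5 remain when any of 18 libraries is left out and 0 with the urothelial libraries left out, and that of Itih4 held in 8 of 33 other settings and that of Fetub in 32. For the first of these, the mock libraries stayed between 1.29 and 10.8 TPM over the 4 weeks while CAC means went from 27.5 to 895 TPM.

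A library far from the others of its group was looked for in 276 tests, each of 1 gene of the text or the mitochondrial share in 1 group. Such a library was found in 28, where chance alone gives about 1 in 20 independent tests. These tests share libraries and are not independent. CAC replicate 3 of week 8 held 9 of the 28. In this library Itih4 was at 151 TPM (636 to 1340 TPM in the other 6), Hp at 582 TPM (5080 to 20500), Fkbp5 at 17.9 TPM (172 to 442), Tsc22d3 at 34.2 TPM (83.4 to 148), Lcn2 at 3.2 TPM (31.9 to 129), Serpina3n at 295 TPM (1300 to 3920), Serpina3m at 7.48 TPM (59.2 to 187) and Fetub at 4.04 TPM (14.9 to 26.8). Its Oxtr was at 49.7 TPM (1.37 to 7.2 in the others), so each of the 9 values lay on the side of the mock group. Without it, limma called 647 genes against mock tissue at 8 weeks in place of 448.

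Mock replicate 2 of week 8 held 3 such values, Lcn2 at 405 TPM (1.44 to 7.02 in the others), Pnpla2 at 900 TPM (1520 to 1840) and Scd1 at 6390 TPM (12100 to 13300). NCAC replicate 3 of week 6 held 4, Hp at 1120 TPM (347 to 466), Cyp51 at 10.4 TPM (22.6 to 27.8), Sprr1a at 0.825 TPM (0 to 0.135) and Upk3a at 0.164 TPM (0 in the others). CAC replicate 1 of week 6 held 3, Mt1 at 3300 TPM (950 to 1280), Scd1 at 11300 TPM (18900 to 22700) and Ccl8 at 82.4 TPM (239 to 339). CAC replicate 2 of week 8 held 2, Nnat at 61.1 TPM (0.52 to 2.31) and Usp50 at 1 TPM (0.0473 to 0.238). Single values far from their group were Cpt1b at 50.7 TPM in NCAC replicate 3 of week 8 (2.8 to 4.61) and Cox7a1 at 168 TPM in CAC replicate 5 of week 8 (48.7 to 78.7). The remaining ones were Lrg1 at 464 TPM in CAC replicate 5 of week 6 (750 to 855), Ccl8 at 79.9 TPM in mock replicate 1 of week 2 (4.69 to 7.36), Lep at 359 TPM in mock replicate 2 of week 2 (161 to 196), Hsd11b1 at 39.8 TPM in mock replicate 5 of week 2 (68.2 to 72.9) and a mitochondrial share of 44.4% in NCAC replicate 1 of week 2 (27.6% to 32.3%). Over the mammary epithelium list, mock replicate 2 of week 8 had a mean log2 level of 5.40, against 0.19 to 1.40 in the other mock libraries of that week. High levels occurred in other arms and weeks too, such as 6.98 in CAC replicate 5 of week 2 and 4.90 in NCAC replicate 3 of week 4. Whether epithelium accounts for the Lcn2 value of that mock library was not tested.

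The 10 largest rises in CAC tissue at 8 weeks include genes of proteins that the liver usually secretes, so liver carried into the libraries was tested as a source. It would bring the other abundant liver transcripts, but 7 of these (Alb, Apoa1, Apoa2, Ttr, Fgb, Ahsg and Serpina1a) had a median log2 change of 0.107 (median absolute deviation 0.763), and Alb fell by 1.95 (SE 0.416), from 9.54 to 1.64 TPM, which argues against it as the whole source. The median is the change of Ttr, at 0.202 TPM in CAC and 0.12 TPM in mock tissue, so it says little by itself. Ahsg (1.8, SE 0.689) and Apoa2 (1.27, SE 0.409) went up without being called, so a small amount of liver stays open. The 7 transcripts averaged from 0.00494 TPM (Fgb) to 10.4 TPM (Ahsg) in CAC tissue of week 8, where Itih4 averaged 895 TPM. Scaling by mitochondrial transcripts is argued against too, since 10 of the 10 genes stayed past the limma threshold with those transcripts left out. Bladder tissue like that of mock mice, as the source of the 10 genes together, is argued against by mock libraries. Their mean log2 level of the 10 genes differed by 0.0214 between the 5 libraries with over 100 TPM of urothelial transcripts and the 15 others (exact permutation p = 0.918, SD 0.364). The mean rise in CAC tissue was 4.57. Mock libraries cannot test bladder tissue of cachectic mice. With the urothelial covariate 4 of the 10 stayed past the threshold and the median change went from 4.12 to 3.81 (3.26 to 6.46). With the urothelial libraries left out 0 of the 10 stayed past it, at a median change of 2.67 (1.42 for Fga to 5.59 for Itih4), but only 2 CAC libraries of week 8 remain then, and 1 of them is replicate 3. The other, replicate 2, held 3.55 TPM of urothelial transcripts and 648 TPM of Itih4. Over the 10 genes the mean log2 level was 8.11 in replicate 2 and 4.73 in replicate 3, against 3.17 to 3.73 in mock libraries of week 8. Fga differs: it was at 1.68 and 1.77 TPM in these 2 libraries and at 22.1 to 1240 TPM in the 5 others. Within those 5, Fga was at 22.1 TPM at the highest urothelial sum (315 TPM) and at 1240 TPM at the lowest (152 TPM). In CAC tissue of week 6 it was at 119 TPM at a sum of 955 TPM and at 3.14 TPM at a sum of 525 TPM. Bladder tissue of cachectic mice as the source of Fga stays open. For the 10 genes together, CAC libraries of week 6 argue against it as the whole source at that week. Their mean log2 level was 7.03 in replicate 4 (urothelial sum 3.65 TPM) and 7.31 in replicate 3 (49.6 TPM). It was 7.05, 7.17 and 8.58 in replicates 2, 5 and 1 (525, 315 and 955 TPM), and 3.60 to 4.69 in mock libraries. Bladder tissue of cachectic mice was not tested singly for the other genes, apart from the Itih4 values above. For these genes, expression by adipose tissue of cachectic mice remains a hypothesis that may account for the rise.

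Urothelial transcripts were higher in CAC than in NCAC tissue at 6 weeks, and bladder tissue carried into some libraries is a candidate source that fits the values. Of the 7 transcripts, Krt5 is also on the mammary epithelium list. Outside these groups, 17 of 52 libraries exceeded 100 TPM in the sum of 7 urothelial transcripts. Of these 17, 17 held at least 6 of the 7 above 1 TPM. Of the 32 libraries with a sum of at most 10 TPM, 0 held 3 or more, which the low sum nearly fixes, so it adds no support. Libraries between 10 and 100 TPM are in neither count. Transcripts made only by tissue of the CAC arm are argued against by 7 libraries of the other 2 arms over the limit. Why 13 of 22 CAC libraries exceeded it, against 7 of 40 of the other arms (Fisher's exact p = 0.00148), stays open: less fat around the bladder in cachectic mice, or a dissection that differed between arms, was not tested. With the urothelial covariate 4 genes in place of 843 were called, but every CAC library of that week (3.65 TPM or more) exceeded every NCAC library (2.22 TPM or less), so this count cannot separate bladder tissue from the arm.

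Matrix genes were lower in CAC than in mock tissue at 8 weeks, and 3 technical explanations were weighed. Scaling is argued against, as at least 14 of the 20 genes were called lower under 2 other scalings, against 13 in the deposited TPM. A lower share of stromal cells is argued against as the whole cause only in so far as 5 stromal markers measure it. The matrix mean fell by 1.84 (exact permutation p = 0.00126) and the mean of the 5 markers by 0.452 (exact permutation p = 0.124). The difference was −1.39 (exact permutation p = 0.00126). Whether these markers follow every kind of stromal cell, or come in part from other cells such as endothelial cells, was not tested. A loss of some stromal cells therefore stays open. A part of the fall may still come from a lower stromal share. With the stromal covariate the matrix count went from 13 to 6 at a median of −1.55, and the lower calls over all genes from 290 to 113. A single mock library rich in stroma is argued against by a median change of −1.57 without mock replicate 2, against −1.89 with it. With regard to the bladder, 4 of the 20 genes were called lower with the urothelial covariate, at a median change of −1.96, and 0 with those libraries left out, at −1.47. A lower expression of matrix genes within stromal cells may explain the fall as a hypothesis, and a change in the kinds of stromal cells stays open as well.

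The counts of called genes were set against 100 groupings of the same libraries, the real one included. For CAC against mock, 1 grouping gave as many at 6 weeks (52 genes, highest other grouping 15) and 3 at 8 weeks (448, highest other 3304). For CAC against NCAC, 2 gave as many at 6 weeks (843, highest other 1347) and 3 at 8 weeks (77, highest other 1675). For the CAC effect at 8 against 2 weeks 3 did (8, highest other 4234). These shares are small for each comparison taken alone, but without adjustment over the 16 comparisons they do not exclude chance. More groupings gave as many for CAC against mock at 2 weeks (1 gene in 6 groupings, highest other 7175) and at 4 weeks (1 gene in 5, highest other 4055). Chance cannot be excluded there either. For the comparisons with 0 calls all 100 groupings gave as many, and the highest other values were 1, 3631, 3611 and 27 for NCAC against mock at 2, 4, 6 and 8 weeks, 3936 and 1305 for CAC against NCAC at 2 and 4 weeks, 568 for the CAC effect at 8 against 6 weeks, 1 for the NCAC effect and 408 for mock tissue at 8 against 2 weeks. Groupings that call many times the real count point to a structure of the samples that the arms do not explain.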

How the results depend on the processing

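The alternatives with mitochondrially encoded genes left out, libraries low in mitochondrial TPM left out, the stromal covariate and both urothelial settings were chosen after seeing the data, and the others were planned. Counts of called genes from limma moved by more than 1.5 times as follows, and where no cause is stated the cause was not tested.

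With a pseudocount of 0.1 the count for CAC against mock at 2 weeks went from 1 to 0. Without a filter it fell to 33 and 223 for CAC against mock at 6 and 8 weeks, to 550 and 34 for CAC against NCAC at 6 and 8 weeks and to 4 for the CAC effect at 8 against 2 weeks, and it was 1 for NCAC against mock at 6 weeks. Median-ratio rescaling gave 0, 188 and 1435 for CAC against mock at 2, 6 and 8 weeks and 218 for CAC against NCAC at 8 weeks. All 62 libraries in 1 fit gave 185 and 986 for CAC against mock at 6 and 8 weeks, 1, 555 and 611 for CAC against NCAC at 4, 6 and 8 weeks and 72 for the CAC effect. Library weights gave 670, 2758 and 1462 for CAC against mock at 2, 6 and 8 weeks, 11, 3307 and 3061 for CAC against NCAC at 2, 6 and 8 weeks, 230 and 1078 for NCAC against mock at 2 and 6 weeks, 777 for the CAC effect at 8 against 2 weeks, 6 for the NCAC effect and 355 for mock tissue at 8 against 2 weeks.

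Leaving out the mitochondrially encoded genes gave 2, 125 and 2072 for CAC against mock at 2, 6 and 8 weeks and 206 for CAC against NCAC at 8 weeks. Leaving out libraries under 22% mitochondrial TPM gave 0, 159 and 296 for CAC against mock at 2, 6 and 8 weeks, 24 for CAC against NCAC at 8 weeks and 3 for the CAC effect, and no value for the 3 comparisons that hold no such library. The stromal covariate gave 2, 0 and 413 for CAC against mock at 2, 4 and 6 weeks and 1919 for CAC against NCAC at 6 weeks. The urothelial covariate gave 0, 10 and 67 for CAC against mock at 2, 6 and 8 weeks and 4 and 1 for CAC against NCAC at 6 and 8 weeks. Leaving out the libraries over 100 TPM of urothelial transcripts, which leaves fewer libraries, gave 0, 0, 5 and 0 for CAC against mock at 2, 4, 6 and 8 weeks, 1, 62 and 0 for CAC against NCAC at 4, 6 and 8 weeks and 0 for the CAC effect at 8 against 2 weeks. The CAC effect at 8 against 6 weeks gave 0 under each alternative run.

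With the urothelial covariate Sprr1a, Upk3a and Psca, themselves 3 of the 7 transcripts in it, reversed to −0.77, −0.73 and −0.74 in CAC against NCAC at 6 weeks, which the construction of the covariate explains. No other named gene reversed: of 2232 values for 101 pairs of a named gene and a comparison, 1447 stayed past the threshold, 782 kept their direction without passing it and 3 reversed. Of the pairs, 6 passed under every alternative.

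With 1 library left out in turn, the counts ran from 0 to 1, 1 to 1, 22 to 159 and 131 to 647 for CAC against mock at 2, 4, 6 and 8 weeks, from 0 to 1, 0 to 1, 210 to 1682 and 7 to 1253 for CAC against NCAC, and from 4 to 68 for the CAC effect at 8 against 2 weeks. They stayed at 0 for the other comparisons. Of the list tests, 156 passed in camera with the preset correlation, 171 with the replicate block added, and 0 with an estimated correlation, with or without that block.

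The replicate numbers do not pair the libraries: of 60 pairs of libraries with the same number 20 had a correlation of their deviations over 0.1 (−0.648 to 0.573), and 15 fitted best with their own number. With the replicate block the counts were 0, 2, 9 and 30 for CAC against mock at 2, 4, 6 and 8 weeks, 815 and 2 for CAC against NCAC at 6 and 8 weeks and 8 for the CAC effect. The unknown read depth limits what can be said of genes near 0 TPM.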

Other observations

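All tests in this part were chosen after the results they address were seen.

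Itih4 differed from mock tissue before limma called it over all genes. At 4 weeks it was at 126 ± 137 TPM (SD, n = 5) in CAC and 3.32 ± 1.24 TPM (n = 5) in mock tissue, 5 of 5 CAC libraries lay above every mock library, and the exact permutation p of 0.00794 is the smallest that 5 against 5 libraries allow (0.0303 adjusted over 24 tests of 3 genes). In NCAC tissue at 6 weeks it lay lower than in mock tissue, at 3.31 ± 0.53 against 7.55 ± 2.35 TPM, with 5 of 5 libraries below every mock library (log2 difference −0.95, exact permutation p = 0.00794, adjusted 0.0303). Ccl8, the 1 gene called at 4 weeks, was not called by limma against mock tissue at 6 or 8 weeks. By the permutation test it was higher in CAC tissue at 6 weeks (235 ± 93.6 against 31.0 ± 33.7 TPM, exact permutation p = 0.00794, adjusted 0.0303) and at 8 weeks (290 ± 249 against 64.8 ± 83.5 TPM, exact permutation p = 0.0152, adjusted 0.0456), where 3 of 7 CAC libraries lay above every mock library. Lep in CAC tissue was at 102 ± 77.2, 84.9 ± 113, 20.01 ± 23.7 and 20.6 ± 19.0 TPM at 2, 4, 6 and 8 weeks, and in mock tissue at 214 ± 82.1, 300 ± 277, 235 ± 172 and 165 ± 172 TPM. Its exact permutation p were 0.0397, 0.0556, 0.0238 and 0.00884, adjusted 0.0953, 0.121, 0.0635 and 0.0303.

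The medians of 10 T cell markers over the 62 libraries ran from 0 TPM for Cd8b1 to 2.23 TPM for Trbc1, and those of 10 markers of B cells and lymph nodes from 0.139 TPM for Cr2 to 84.9 TPM for Ccl21a. The median was 0.0836 TPM for Cd3e, 0.0854 TPM for Cd3d, 0.226 TPM for Cd3g and 0.0163 TPM for Cd8a, and Cd3e exceeded 1 TPM in 4 libraries, Trbc1 in 60. The B cell markers Cd79a and Cd79b had medians of 2.55 and 2.5 TPM and exceeded 1 TPM in 57 and 59 libraries, Ms4a1 (median 0.462 TPM) in 12. The melanocyte genes Tyr and Tyrp1 had medians of 0 and reached at most 0.00918 and 0.0653 TPM, and Pmel and Dct had medians of 0.723 and 1.78 TPM.

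Of 14 clock genes 10 passed adjusted over the list alone between NCAC and mock tissue at 2 weeks and 0 over all genes, and a different time of day of collection was tested as a hypothesis with genes that peak in the evening and in the morning. The evening minus the morning mean differed by 1.93 on the log2 scale (exact permutation p = 0.00794, the smallest that 5 against 5 libraries allow, and 0.0953 adjusted over 12 comparisons), from 1.04 for the evening and −0.896 for the morning genes. CAC differed from NCAC tissue by −1.90 at that week (exact permutation p = 0.0476, adjusted 0.286), and CAC from mock tissue by 0.03. A shifted collection time as a hypothesis cannot be told apart from an effect of the cells, since no collection time is stated and the adjusted p misses the threshold.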
